A study of Mus musculus with 12 samples.

How the data were processed

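Poly(A) RNA of interscapular brown adipose tissue from 12 mice, 6 ctrl and 6 cold, was sequenced as strand-specific libraries with 50 nt paired-end reads, per the labels' protocols. The submitters' processing notes name bcl2fastq, cutadapt, Salmon and the GRCm38 genome, without versions. The annotation release given to Salmon is not given in the sources used here. Each deposited file holds 140658 transcripts for 1 animal with estimated counts (the expected count of reads per transcript, not normalized) and TPM (transcript abundance scaled by effective length to a fixed total), per the file headers. Estimated counts in the deposited files were not whole for 29.5% to 32.6% of values per library, and they were rounded to whole numbers after summing. Effective lengths exceeded the annotated length for 9.26% to 15.8% of the 88552 transcripts with reads, depending on the library.

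Transcripts were tied to genes by identifier without version in GENCODE M21, an annotation of GRCm38. Of the 140658 transcripts 140137 matched, 139921 of them with the same version, giving 54356 genes. The 521 unmatched transcripts held 0.0866% to 0.152% of reads and were left out. There were 103 symbols used by more than 1 gene, which were kept apart by identifier. Coordinates are those of GENCODE M21 on GRCm38. Groups were taken from the treatment label and animals from the mouse number. The mouse numbers differ between the groups, so animals were not paired. The labels name no batch. The least different pair of libraries within a group had a chi-square per degree of freedom of 13.8 over 12750 genes with a mean of at least 20 reads, so no library was a copy of another. Correlations of log2 CPM within groups ran from 0.955 to 0.984.

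The tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Gene counts were the sums of transcript estimates. Genes were kept by edgeR's filterByExpr (minimum count 10), scaled by TMM, and tested for cold against ctrl with edgeR's robust quasi-likelihood fit, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM are counts scaled to a common TMM library size, with mean and SD over 6 animals. The biological coefficient of variation was 20.6%. Transcripts were tested in the same way. Usage was tested with edgeR's diffSpliceDGE gene test in genes with at least 2 transcripts past the filter, and usage itself is a transcript's share of its gene's summed TPM as deposited. TPM of single genes and transcripts were not compared between groups, and TPM shares of the library served only as an alternative, because transcripts with an effective length under 50 nt held 55.2% of TPM in ctrl 2 and 2.36% to 8.41% elsewhere. The ctrl means of usage include ctrl 2 without correction, and whether this shifted usage there was not tested. The usage test itself works on counts, and without ctrl 2 it called 69 genes against 88.

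The 29 lists comprised 20 of biology and 9 of cell type markers. They were tested with limma's camera on the gene fit with a preset correlation of 0.01, and again with an estimated correlation and with fry, which does not compare a list with other genes. Library values were compared with exact two-sided permutation tests over all 924 assignments of 6 against 6 animals, adjusted over 14 values, and 4 further shares were added later. The named genes were 8 fixed ones (Ucp1, Dio2, Ppargc1a, Adrb3, Elovl3, Pnpla2, Gk and Fasn), the 6 largest rises and 6 largest falls among non-overlapping called genes with a mean log2 CPM of at least 2, 2 members of each called biology list and 1 of each other list by smallest p. For usage they were the 8 genes of smallest p with a non-overlapping change of at least 0.1, and Ppargc1a, Pparg, Lpin1, Acsl5, Cars2 and Adtrp. Cars2 entered by both parts. A few genes that the rule or the lists name are not reported here. Members outside the rule were named after their values were seen.

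Alternatives were RLE factors and library totals as scaling, DESeq2 and limma-voom as tests, no filter and a stricter filter, an effective length offset, mitochondrial genes removed, the mean log2 CPM of skeletal muscle markers as a covariate, Simes and limma's diffSplice for usage, a usage minimum of 0.05, TPM shares for library values, and each animal left out in turn. Leaving out ctrl 2 and cold 15 together, removing Gm42418 and Lars2, the muscle covariate for usage, library totals for lists and the white adipocyte share without Npr3 were added after seeing the data. Work was done in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

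The tests were tried on counts simulated from the real means, spread and library sizes with 200 features changed. For genes (13683 tested) 48.4%, 72.5% and 96.8% of 1.5-fold, 2-fold and 4-fold changes were found with 6 false calls. For transcripts (27691 tested) it was 9.68%, 18.8% and 63.0% with 2 false calls. For usage (6620 genes tested, 188 of them switched by up to 30 percentage points of the gene's reads) diffSpliceDGE found 134 with 34 false calls, Simes 80 with 25 and limma's diffSplice 140 with 19. All 5 raised lists of 20 were called with 0 false calls, in counts drawn independently between genes.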

Results

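Interscapular brown adipose tissue, the fat depot between the shoulder blades that produces heat in rodents, was profiled in 12 male C57BL/6N mice aged 20 weeks. The labels call 6 animals cold and 6 ctrl. The treatment text, 24 h of single housing at 4 °C, is attached to the ctrl animals as well as the cold ones, and is read here as meant for the animals labelled cold. The husbandry text gives 22 to 24 °C for the colony, and how the ctrl animals were housed in the final day is not stated separately. If they were not housed singly, single housing cannot be told apart from cold. The series text gives n = 3 for cold where the labels give 6, and the extraction text names eWAT where the tissue label is brown fat; the labels were followed. Every animal has its own mouse identity number, so the p-values of the gene, transcript, usage and library tests measure the spread between animals. PolyA RNA was read in 50 nt pairs from strand-specific libraries. The estimated reads per library were 18.96, 24.5, 26.8, 17.6, 19.1 and 16.0 M for ctrl 2, 5, 6, 9, 10 and 14. For cold 4, 7, 11, 12, 15 and 16 they were 31.4, 18.2, 17.7, 19.3, 20.8 and 17.0 M. The group means were 20.5 ± 4.23 and 20.7 ± 5.41 M reads (SD, n = 6 each; exact two-sided permutation p = 0.937). Groups lay on opposite sides of the first principal component, which held 37.5% of the variance of log2 CPM, with 20.4% on the second. The second separated low from high mouse numbers within each group. Ctrl 2, 5 and 6 lay at 10.45, -9.21 and 15.7, and ctrl 9, 10 and 14 at -22.3, -21.2 and -23.8. Cold 4 and 7 lay at 28.5 and 27.8, and cold 11, 12, 15 and 16 between -16.8 and 9.97. No batch is labelled, none was modelled, and the cause was not tested.

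**Figure D1:**
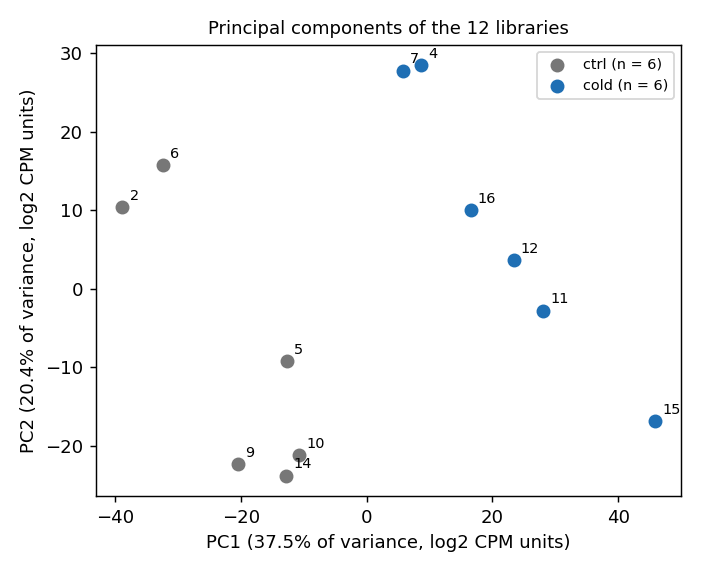
First and second principal components of log2 CPM, in log2 CPM units, one point per animal with its mouse number, ctrl in grey and cold in blue (n = 6 each). The first component holds 37.5% and the second 20.4% of the variance, and all cold animals lie to the right of all ctrl animals.

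The comparison of cold with ctrl asks which genes of brown adipose tissue differ in level after 24 h at 4 °C. Ppargc1a, the coactivator that drives mitochondrial gene programmes, rose from 53.7 ± 8.60 to 316 ± 73.3 CPM (SD, n = 6 each), a log2 fold change of 2.55 ± 0.16 (SE; adjusted p = 3.08e-08, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Dio2, the enzyme that activates thyroid hormone, rose from 117 ± 60.7 to 427 ± 50.2 CPM, by 1.86 ± 0.31 on the log2 scale (adjusted p = 8.78e-04, edgeR). Elovl3, a fatty acid elongase, rose from 134 ± 71.8 to 688 ± 94.4 CPM, and Gk, glycerol kinase, from 333 ± 97.5 to 772 ± 84.6 CPM (log2 fold changes 2.36 ± 0.28 and 1.21 ± 0.18; adjusted p = 5.82e-05 and 1.62e-04, edgeR). Fasn, fatty acid synthase, fell from 29960 ± 6376 to 10980 ± 3754 CPM, a log2 fold change of -1.45 ± 0.25 (adjusted p = 7.36e-04, edgeR). The ranges of the groups did not overlap for any of these genes.

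Ucp1, which encodes the uncoupling protein of brown adipocyte mitochondria, stood at 8629 ± 1588 CPM in ctrl and 10070 ± 769 CPM in cold (log2 fold change 0.22 ± 0.11, adjusted p = 0.135, edgeR). Without ctrl 6, whose 11130 CPM was the highest ctrl value, the log2 fold change was 0.31 with an adjusted p of 0.0220, and with scaling by library totals it was 0.31 with an adjusted p of 0.0369 (edgeR). Adrb3, the beta-3 adrenergic receptor, was at 135 ± 21.6 and 141 ± 19.1 CPM (0.06 ± 0.11, adjusted p = 0.707, edgeR). Pnpla2, adipose triglyceride lipase, was at 2772 ± 343 and 2457 ± 188 CPM (-0.17 ± 0.09, adjusted p = 0.164, edgeR). Ucp1 lies on chromosome 8 at 83290352 to 83298452, Ppargc1a on chromosome 5 at 51454250 to 51567726, Dio2 on chromosome 12 at 90724552 to 90738438 and Fasn on chromosome 11 at 120805846 to 120824547 (GRCm38, GENCODE coordinates of the whole gene).

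**Figure D2:**
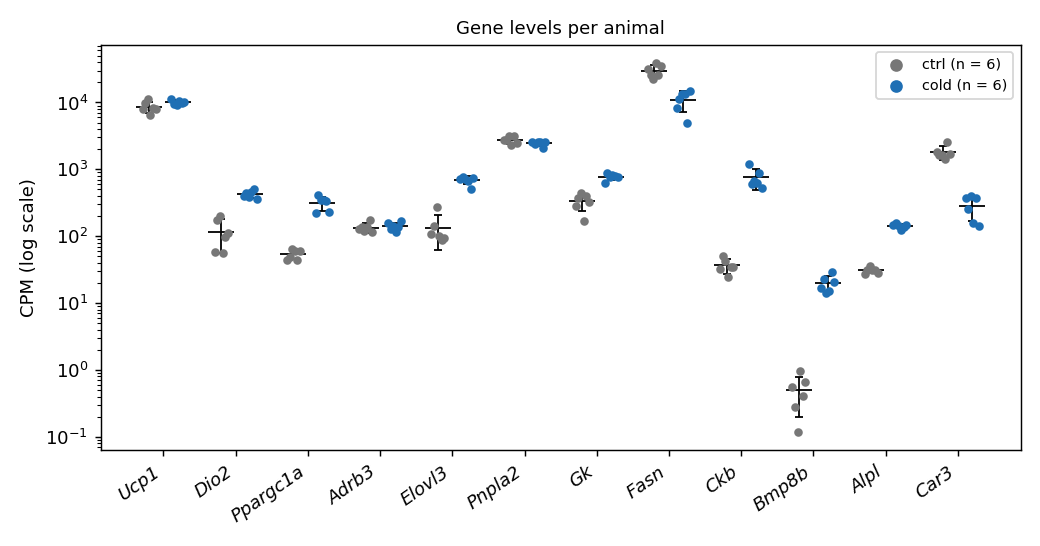
Level of 12 genes in CPM on a log axis, one point per animal, ctrl in grey and cold in blue (n = 6 each), with bars for the mean and SD. Ppargc1a, Dio2, Elovl3, Gk, Ckb, Bmp8b and Alpl lie higher and Fasn and Car3 lower in every cold animal than in every ctrl animal, while the ranges of Ucp1, Adrb3 and Pnpla2 overlap.

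Among genes with a mean of at least 2 on the log2 CPM scale and no overlap between the groups, the 6 largest rises were those of Bdh1, Kcnh6, Cyp2b10, Bmp8b, Cpne5 and Ckb. Bdh1, a ketone body dehydrogenase, went from 0.156 ± 0.098 to 25.04 ± 19.3 CPM, a log2 fold change of 7.32 ± 0.64 (adjusted p = 9.97e-06, edgeR). Kcnh6, a voltage-gated potassium channel, went from 0.062 ± 0.11 to 9.96 ± 3.64 CPM (6.96 ± 0.51, adjusted p = 4.76e-07, edgeR). Cyp2b10, a cytochrome P450, and Bmp8b, a secreted bone morphogenetic protein, rose by 5.55 ± 0.79 and 5.38 ± 0.33 on the log2 scale (adjusted p = 3.82e-04 and 8.96e-08, edgeR). These 4 genes had ctrl means at or under 0.5 CPM, so their folds rest on few ctrl reads. Cpne5, a copine, rose from 2.56 ± 1.81 to 66.5 ± 11.9 CPM, and Ckb, the brain-type creatine kinase, from 36.5 ± 8.83 to 755 ± 257 CPM (4.64 ± 0.40 and 4.37 ± 0.24; adjusted p = 8.96e-06 and 5.74e-08, edgeR). Ckb lies on chromosome 12 at 111669361 to 111672338, Bmp8b on chromosome 4 at 123105165 to 123132099 and Bdh1 on chromosome 16 at 31422280 to 31458901.

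The 6 largest falls were those of Slc2a5, Ntrk3, Hcar1, Atp4b, Lctl and Car3. Slc2a5, the fructose transporter, fell from 46.8 ± 29.0 to 3.76 ± 1.44 CPM, a log2 fold change of -3.63 ± 0.50 (adjusted p = 2.90e-04, edgeR). Ntrk3, a neurotrophin receptor, fell from 183 ± 52.8 to 17.8 ± 4.86 CPM (-3.36 ± 0.23, adjusted p = 6.45e-07, edgeR). Hcar1, the lactate receptor, fell from 26.1 ± 6.95 to 3.72 ± 1.15 CPM (-2.79 ± 0.21, adjusted p = 4.76e-07, edgeR). Atp4b, the beta subunit of the gastric proton pump, and Lctl, a lactase-like protein, changed by -2.74 ± 0.33 and -2.71 ± 0.23 (adjusted p = 2.94e-05 and 1.80e-06, edgeR). Car3, a carbonic anhydrase abundant in fat, fell from 1803 ± 403 to 283 ± 115 CPM (-2.67 ± 0.29, adjusted p = 2.57e-05, edgeR). Slc2a5 lies on chromosome 4 at 150119283 to 150144169, Ntrk3 on chromosome 7 at 78175959 to 78738012 and Car3 on chromosome 3 at 14863512 to 14872523.

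Over all 13876 genes tested, 2246 were higher and 2134 lower in cold at an adjusted p under 0.05 (edgeR), which is 31.6% of them. At least 2-fold changes numbered 349 higher and 351 lower. Protein-coding genes made up 2137 of the higher and 1882 of the lower genes. Of 831 long non-coding RNA genes tested, 74 were higher and 193 lower. The groups did not overlap for 2261 genes, 16.3% of those tested against 0.217% by chance, and 2243 of these passed the test. With libraries scaled by their totals in place of TMM factors, the share of higher among the called genes went from 51.3% to 67.3% and the lower genes numbered 1409, while the median of all genes moved from -0.01 to 0.08 on the log2 scale. Without ctrl 2 and cold 15, whose unusual read shares are given with the library values, 1842 genes were higher and 1634 lower, a choice made after seeing the data.

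Gene groups were described with lists fixed beforehand, each tested against all other genes with camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over 29 lists. At that preset correlation 28 of 100 regroupings of the animals called at least as many lists as the 11 called here, so the counts of members carry the description. They are to be read against all 13876 genes, of which 2246 were higher and 2134 lower, or 31.6% called. Lists near that share, such as sterol synthesis and the tricarboxylic acid cycle below, do not stand out from other genes by their counts. In the thermogenic and brown adipocyte list, 12 of 25 members rose, 1 fell and 12 did not pass the test, with the same 12, 1 and 12 when adjusted over the list alone. Besides Bmp8b, Ppargc1a, Dio2 and Elovl3, the risers included Gdf15, a stress-induced cytokine, at 4.47 ± 0.43, and Cidea, a lipid droplet protein, at 0.48 ± 0.12 on the log2 scale. Gdf15 went from 0.199 to 4.41 CPM, so its fold also rests on few ctrl reads. The member that fell was Nrg4, a secreted growth factor, from 126 to 83.1 CPM (-0.60 ± 0.06). The list's median was 0.23, with adjusted p = 3.46e-05 (camera) and adjusted p = 0.0123 with an estimated correlation, the only list whose call held in that form. Gdf15, Cidea and Nrg4 and the members named from here on without a full set of values were picked after their values were seen.

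In the creatine and calcium cycling list, 6 of 12 members rose and 1 fell, the same 6 and 1 when adjusted over the list alone (camera adjusted p = 3.14e-05; adjusted p = 0.0885 with an estimated correlation). Alpl, tissue-nonspecific alkaline phosphatase, had the smallest p of all genes, rising from 30.8 ± 2.73 to 142 ± 10.4 CPM (2.20 ± 0.08, adjusted p = 3.80e-11, edgeR). Ckb rose as above, as did Letm1 (0.56), Slc6a8, the creatine transporter (0.52), Atp2a2, a calcium pump of the endoplasmic reticulum (0.47), and Mcu (0.32). Gamt, which makes creatine, fell from 2.88 to 1.36 CPM (-1.08).

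Of 17 members of the list of fatty acid synthesis and desaturation, 12 fell and none rose, with the same counts adjusted over the list alone. Slc25a1, the mitochondrial citrate carrier, fell from 885 ± 196 to 187 ± 43.5 CPM (-2.24 ± 0.17, adjusted p = 2.24e-07, edgeR). Acaca, acetyl-CoA carboxylase, fell from 3535 ± 752 to 1251 ± 275 CPM (-1.50 ± 0.16, adjusted p = 8.16e-06, edgeR). Acly, Scd1 and Me1 fell by 2.25, 1.31 and 1.22 on the log2 scale. The median of the list was -0.96 (camera adjusted p = 3.88e-06; adjusted p = 0.43 with an estimated correlation, which was 0.51 between members). Skeletal muscle markers, given with the cell types, were more abundant in some cold libraries, and with their score as a covariate 11 of the 12 members stayed lower.

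Genes of triglyceride synthesis and lipid droplets rose more often than they fell, with 10 of 23 members higher and 3 lower, the same counts when adjusted over the list alone (camera adjusted p = 0.0335; adjusted p = 0.511 with an estimated correlation; 0.0739 without cold 4). Agpat3, an acyltransferase, rose from 622 ± 38.4 to 969 ± 30.6 CPM (0.64 ± 0.07, adjusted p = 3.47e-06, edgeR). Gpam, which starts glycerolipid synthesis, rose from 589 ± 81.8 to 1051 ± 96.0 CPM (0.84 ± 0.10, adjusted p = 9.78e-06, edgeR). The members that fell were Pck1 (-0.94), Plin4 (-0.44) and Agpat2 (-0.34). For fatty acid uptake and activation, 10 of 16 members rose and 3 fell, or 11 and 4 when adjusted over the list alone (camera adjusted p = 0.0221; adjusted p = 0.43 with an estimated correlation). Fabp3, a fatty acid binding protein, rose from 769 ± 225 to 2431 ± 499 CPM (1.66 ± 0.19, adjusted p = 2.19e-05, edgeR), and Vldlr, a lipoprotein receptor, from 123 ± 8.79 to 218 ± 26.4 CPM (0.82 ± 0.09, adjusted p = 3.83e-06, edgeR). Lpl, lipoprotein lipase, rose from 5018 to 11720 CPM, whereas Fabp5 (-1.20), Acsl3 (-0.79) and Slc27a1 (-0.73) fell.

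In the fatty acid oxidation list 7 of 20 members rose and 2 fell, or 9 and 2 when adjusted over the list alone, and the list as a whole did not pass (camera adjusted p = 0.062; adjusted p = 0.766 with an estimated correlation). It passed camera without ctrl 2, 6 or 10 or cold 15 (adjusted p = 0.0412, 0.0450, 0.0440 and 0.0428), with the muscle score as a covariate (0.0448), with library totals (0.0404) and without both ctrl 2 and cold 15 (0.0255). Cpt1a, which admits long-chain fatty acids to mitochondria, rose from 23.0 ± 3.36 to 85.3 ± 13.2 CPM (1.89 ± 0.12, adjusted p = 1.78e-08, edgeR), while Eci1 (-0.66) and Acaa2 (-0.49) fell. Sterol synthesis genes were split, with 5 of 21 higher and 3 lower, the same when adjusted over the list alone (camera adjusted p = 0.456). Hsd17b7 rose from 14.4 ± 1.91 to 31.9 ± 6.30 CPM (1.15 ± 0.13, adjusted p = 9.53e-06, edgeR), and Srebf2 (0.36) and Hmgcs1 (0.34) were among the other risers. The sterol-regulated Insig1 fell by 1.09 on the log2 scale, with Pmvk (-0.58) and Mvk (-0.31).

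Of the 13 protein genes encoded by mitochondrial DNA, 8 fell and none rose, or 10 and none when adjusted over the list alone (median -0.55; camera adjusted p = 1.05e-03; adjusted p = 0.449 with an estimated correlation). mt-Cytb fell from 24770 ± 4081 to 14950 ± 1713 CPM (-0.73 ± 0.11, adjusted p = 8.44e-05, edgeR) and mt-Nd6 from 1009 ± 101 to 625 ± 109 CPM (-0.69 ± 0.11, adjusted p = 1.93e-04, edgeR). With the skeletal muscle score as a covariate all 8 stayed lower. Nuclear genes for respiratory chain subunits did not pass as a list, with 1 of 46 higher and 7 lower, or 1 and none when adjusted over the list alone (camera adjusted p = 0.062; 1.20e-03 without cold 4, and 0.0301, 0.0440 and 0.0231 without ctrl 9, 10 or 14). The riser was Cycs, cytochrome c, from 258 ± 31.3 to 366 ± 46.6 CPM (0.50 ± 0.10, adjusted p = 1.15e-03, edgeR). In the tricarboxylic acid cycle list 2 of 17 members rose (Idh3a 0.48, Dld 0.26) and 4 fell, the same counts when adjusted over the list alone (camera adjusted p = 0.245). Pdhb, a pyruvate dehydrogenase subunit, fell from 1156 ± 112 to 708 ± 83.0 CPM (-0.71 ± 0.09, adjusted p = 2.57e-05, edgeR), as did Pdha1 (-0.57), Pcx (-0.49) and Suclg2 (-0.42).

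Among genes of glucose uptake and glycolysis, 11 of 20 rose and none fell, or 12 and 1 when adjusted over the list alone (camera adjusted p = 0.0221; adjusted p = 0.449 with an estimated correlation). Pfkp, a phosphofructokinase, rose from 140 ± 11.4 to 187 ± 15.3 CPM (0.42 ± 0.08, adjusted p = 5.15e-04, edgeR), and Pgam1, a phosphoglycerate mutase, from 940 ± 41.7 to 1214 ± 73.1 CPM (0.37 ± 0.07, adjusted p = 6.60e-04, edgeR). The risers also included Pdk4 (0.46) and Pdk2 (0.21), kinases that restrain pyruvate dehydrogenase.

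In the unfolded protein response list 10 of 17 members rose and 1 fell, the same when adjusted over the list alone (camera adjusted p = 1.07e-04; adjusted p = 0.449 with an estimated correlation). Atf3, a stress-induced transcription factor, rose from 2.53 ± 0.53 to 12.0 ± 2.84 CPM (2.25 ± 0.18, adjusted p = 1.37e-07, edgeR), and Calr, a calcium-binding chaperone, from 256 ± 24.3 to 477 ± 42.8 CPM (0.90 ± 0.09, adjusted p = 9.78e-07, edgeR). Asns, which makes asparagine, fell (-0.33). Of 13 heat shock protein genes 8 rose and none fell, or 10 and none when adjusted over the list alone (camera adjusted p = 5.56e-04; adjusted p = 0.43 with an estimated correlation). Bag3, a co-chaperone, rose from 52.1 ± 3.00 to 86.0 ± 11.5 CPM and Hsp90aa1 from 182 ± 36.7 to 316 ± 17.0 CPM (0.72 ± 0.08 and 0.80 ± 0.11; adjusted p = 9.15e-06 and 4.48e-05, edgeR).

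In the circadian clock list, 7 of 17 members fell and 3 rose, or 11 and 4 when adjusted over the list alone (camera adjusted p = 0.0109; adjusted p = 0.185 with an estimated correlation). Per3, a period gene of the clock, fell from 75.9 ± 7.38 to 33.3 ± 6.35 CPM (-1.19 ± 0.11, adjusted p = 9.27e-07, edgeR). The risers were Arntl (1.24), Nfil3 (0.64) and Nr1d1 (0.53). The time of day of tissue collection is not in the labels. Of 12 interferon response genes 5 fell and none rose, or 6 and none when adjusted over the list alone (camera adjusted p = 0.0335; adjusted p = 0.476 with an estimated correlation; 0.0501 with the skeletal muscle covariate and 0.0565 without cold 11). Rsad2 fell from 15.2 ± 0.71 to 8.002 ± 1.72 CPM (-0.92 ± 0.12, adjusted p = 2.94e-05, edgeR), with Ddx58 (-0.62 ± 0.12, adjusted p = 7.84e-04, edgeR), Irf7 (-0.55), Bst2 (-0.48) and Ifih1 (-0.44). With an offset for effective transcript length Ddx58 was at -0.29 and no longer passed (adjusted p = 0.379, edgeR).

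Of the lists that camera did not call, the cAMP-responsive early genes had 6 of 14 members higher and 1 lower, or 7 and 1 when adjusted over the list alone (adjusted p = 0.084, camera; 0.0427 without ctrl 10 and 0.0307 without ctrl 9). Their member with the smallest p, the nuclear receptor Nr4a2, rose from 21.1 ± 4.91 to 36.9 ± 3.34 CPM (0.80 ± 0.13, adjusted p = 2.34e-04, edgeR), but with an offset for effective transcript length it was at 0.16 (adjusted p = 0.694, edgeR). Nr4a1 (1.62) and Nr4a3 (1.10) rose by more, and Ier3 fell (-0.60). In the extracellular matrix list 2 of 19 members rose and 8 fell, the same when adjusted over the list alone (adjusted p = 0.189, camera). Both risers encode basement membrane collagen, Col4a2 from 577 ± 50.7 to 1086 ± 175 CPM (0.91 ± 0.11, adjusted p = 8.64e-06, edgeR) and Col4a1 (0.80), while the fibrillar collagens Col3a1 (-0.88), Col1a2 (-0.61) and Col1a1 (-0.51) fell. Splicing regulators had 5 of 20 higher and 5 lower, or 6 and 5 when adjusted over the list alone (adjusted p = 0.989, camera; median and mean had opposite signs), and Cirbp, the cold-inducible RNA-binding protein, fell from 26.7 ± 3.78 to 17.4 ± 1.79 CPM (-0.61 ± 0.10, adjusted p = 2.13e-04, edgeR). The cell cycle list had 2 of 14 members higher, Tyms (1.06 ± 0.13, adjusted p = 1.43e-05, edgeR) and Rrm2 (0.95), or 1 when adjusted over the list alone (adjusted p = 0.189, camera). Among 23 cytosolic ribosomal proteins Rpl5 rose (0.81 ± 0.17, adjusted p = 1.38e-03, edgeR) and Rps19 (-0.57) and Rps24 (-0.45) fell, the same when adjusted over the list alone (adjusted p = 0.363, camera; 0.0155 without cold 4). Ribosomal protein genes have many near-identical pseudogene copies, so their reads are uncertain.

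**Figure D3:**
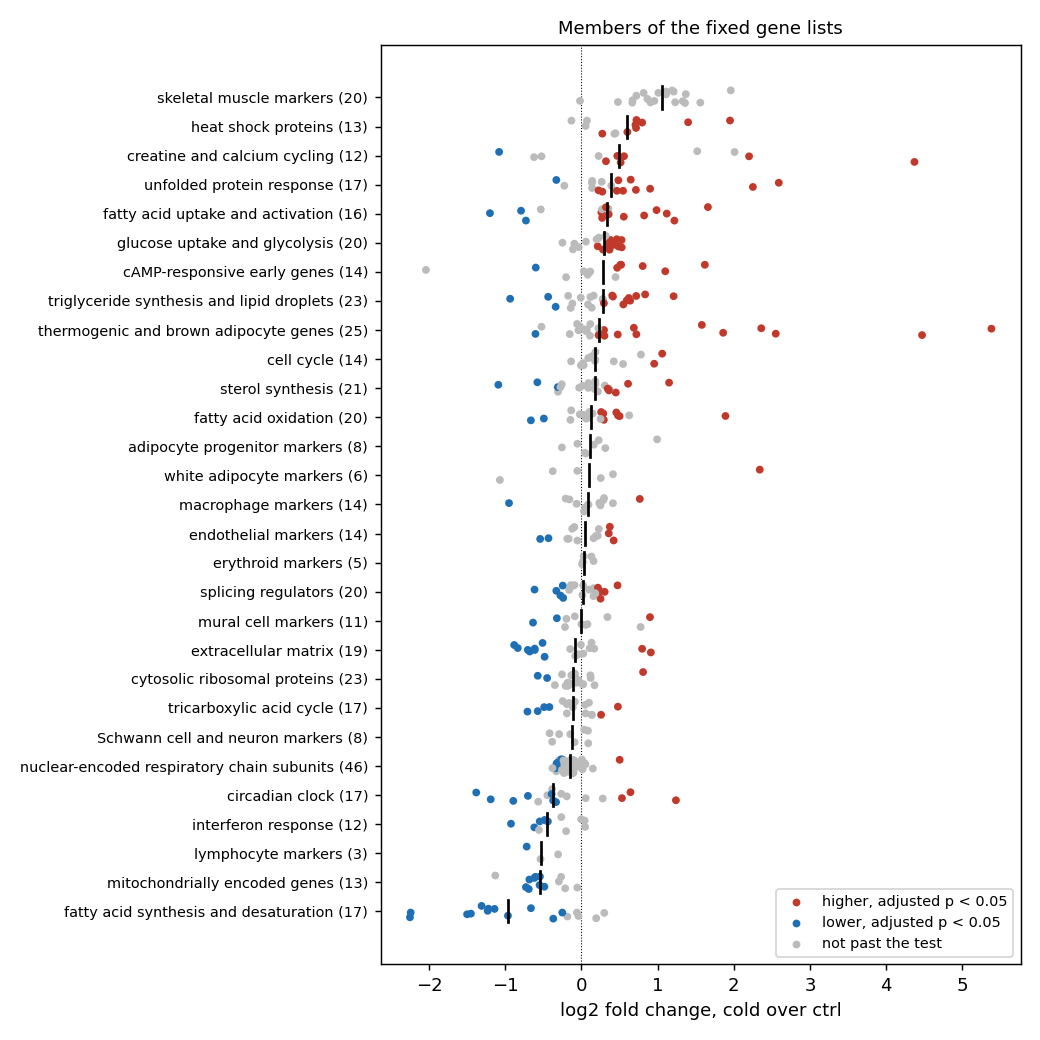
Log2 fold change, cold over ctrl, of the tested members of 29 gene lists (number tested in parentheses), red for higher and blue for lower at an adjusted p under 0.05 (edgeR), grey for the rest, with a black bar at the list's median. Fatty acid synthesis has the lowest median (-0.96, 12 of 17 lower) and skeletal muscle markers the highest (1.06), none of whose 20 members passed the test.

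Markers of other cell types were tested in the same way, and none of these 9 lists passed camera. Skeletal muscle markers had a median of 1.06 with none of 20 members past the test, with or without adjustment over the list alone (adjusted p = 0.296, camera). Mb, myoglobin, was at 16.3 ± 12.0 CPM in ctrl and 63.3 ± 70.3 CPM in cold, from 1.82 CPM in ctrl 6 to 201 CPM in cold 15 (1.96 ± 0.84, adjusted p = 0.106, edgeR; 0.0403 with DESeq2). With the skeletal muscle score, which includes Mb, as a covariate, Mb was at 1.17 ± 0.16 (adjusted p = 1.02e-04, edgeR). Mb thus rose beyond what the score accounted for. Of 6 white adipocyte markers tested Npr3, a natriuretic peptide receptor, rose from 92.0 ± 28.5 to 464 ± 86.6 CPM (2.34 ± 0.20, adjusted p = 1.24e-06, edgeR), and the other markers did not pass (list adjusted p = 0.189, camera). Endothelial markers were split, with Eng (0.42), Vwf (0.37) and Pecam1 (0.36) higher and Tek (-0.54) and Tie1 (-0.43 ± 0.08, adjusted p = 7.93e-04, edgeR) lower of 14 (list adjusted p = 0.957, camera). Macrophage markers had Cd68 higher (0.77) and Cd14 lower (-0.95 ± 0.26, adjusted p = 0.0111, edgeR) of 14 (list adjusted p = 0.713, camera). Mural cell markers had Cnn1 higher (0.90) and Rgs5 (-0.64 ± 0.09, adjusted p = 5.81e-05, edgeR) and Myh11 (-0.32) lower of 11 (list adjusted p = 0.835, camera; its median and mean had opposite signs). Ighm, an immunoglobulin chain, fell among 3 lymphocyte markers tested (-0.72 ± 0.18, adjusted p = 6.26e-03, edgeR; list adjusted p = 0.35, camera). No member passed among 8 adipocyte progenitor, 8 Schwann cell and neuron and 5 erythroid markers (list adjusted p = 0.598, 0.693 and 0.906, camera). The members with the smallest p among the progenitor and erythroid markers were Ly6a (0.31 ± 0.16, adjusted p = 0.152, edgeR; 0.00484 without ctrl 6) and Alas2 (0.16 ± 0.16, adjusted p = 0.484, edgeR). Counts adjusted over the list alone were the same as over all genes for each of these cell type lists.

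Shares of reads per library showed which libraries differed in composition. Mitochondrially encoded protein genes took 18.3% ± 2.61 of reads in ctrl and 14.0% ± 1.14 in cold (SD, n = 6 each; exact two-sided permutation p = 4.33e-03, adjusted over 14 library values 0.0202), and with shares of TPM the difference of -4.62 points did not pass (adjusted exact p = 0.389), a comparison that includes ctrl 2, where transcripts of effective length under 50 nt held 55.2% of TPM. The 10 most abundant genes of each library took 24.1% ± 3.34 and 16.8% ± 1.09 (exact p = 2.16e-03, adjusted 0.0152). Genes that fell, such as mt-Co1 (36190 CPM in ctrl) and Fasn (29960 CPM), are among the most abundant, so this is not a separate result. The highest value was 28.8% in ctrl 2, and without ctrl 2 the difference went from -7.33 to -6.40 points (adjusted exact p = 0.0101). White adipocyte markers took 0.0173% ± 5.83e-03 and 0.0557% ± 8.46e-03 (exact p = 2.16e-03, adjusted 0.0152), but without Npr3 (464 CPM in cold) they took 8.36e-03% ± 4.09e-03 and 7.76e-03% ± 2.97e-03 (exact p = 0.768, adjusted 0.886), so the rise of this share rests on 1 gene. Skeletal muscle markers took 0.0967% ± 0.070 in ctrl and 0.217% ± 0.252 in cold, from 0.0196% in ctrl 6 to 0.689% in cold 15 (exact p = 0.335, adjusted 0.587). Without cold 15 the difference went from 0.120 to 0.0255 points. Lymphocyte markers took 1.54e-03% ± 4.01e-04 and 1.04e-03% ± 2.62e-04 (exact p = 0.0152, adjusted 0.0530; 0.0303 without ctrl 2 and 0.0227 without cold 16). Endothelial markers stood at 0.142% and 0.161%, macrophage markers at 8.23e-03% and 9.67e-03%, mural cell markers at 0.0819% and 0.0805%, and adipocyte progenitor markers at 9.74e-03% and 0.0112% (adjusted exact p = 0.206, 0.404, 0.886 and 0.502). Schwann cell and neuron markers stood at 8.08e-03% and 8.26e-03% and erythroid markers at 0.0782% and 0.0844% (adjusted exact p = 0.886 for each). Gm42418 and Lars2, a pair of loci that collect ribosomal RNA reads, took 11.4% of reads in ctrl 2 against 0.137% to 0.319% in the other ctrl libraries and up to 1.56% in cold 12.

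At the level of single transcripts the comparison asks which annotated isoforms differ in level. Of 30416 transcripts tested, 1886 were higher and 1237 lower in cold at an adjusted p under 0.05 (edgeR), 487 and 438 of them at least 2-fold. The called transcripts belonged to 2663 genes, of which 2425 also passed the gene test, and 29 genes had transcripts that passed in opposite directions. Alpl-201, a protein-coding transcript of Alpl with the smallest p of all transcripts, rose by 2.19 ± 0.09 on the log2 scale (adjusted p = 1.59e-07, edgeR). Cars2-205, annotated as a target of nonsense-mediated decay, rose by 4.12 ± 0.43 and the protein-coding Cars2-201 by 1.00 ± 0.16 (adjusted p = 1.13e-04 and 1.46e-03, edgeR). Without ctrl 2 and cold 15 the counts were 1236 higher and 788 lower, and with DESeq2 1906 were lower. In simulated data the transcript test found 18.8% of 2-fold and 63.0% of 4-fold changes, against 72.5% and 96.8% for genes, so a transcript that did not pass is not shown to be stable.

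Transcript usage, the share of a gene's TPM held by each of its transcripts, asks whether the mix of isoforms changed beside the level of the gene. In Tspan18, a tetraspanin gene, the short Tspan18-205 went from 5.48% ± 3.11 of the gene's TPM in ctrl to 49.7% ± 9.87 in cold (SD, n = 6 each), while the protein-coding Tspan18-202 went from 62.7% ± 7.93 to 35.1% ± 8.44 (usage adjusted p = 1.03e-12, edgeR's diffSpliceDGE). In Rab34, a small GTPase, the protein-coding Rab34-201 went from 32.0% ± 4.65 to 56.4% ± 5.80 and the protein-coding Rab34-203 from 38.6% ± 5.46 to 20.2% ± 3.66 (usage adjusted p = 3.64e-06, diffSpliceDGE), with the gene's log2 fold change at 0.00 ± 0.12 (adjusted p = 0.985, edgeR). Cars2, the mitochondrial cysteinyl-tRNA synthetase, rose 2.11 ± 0.12 on the log2 scale as a gene (adjusted p = 4.08e-09, edgeR), and its decay-annotated Cars2-205 went from 9.12% ± 5.50 to 36.7% ± 4.37 as Cars2-201 went from 43.5% ± 12.4 to 18.3% ± 4.49 (usage adjusted p = 2.02e-07, diffSpliceDGE). In all, 88 of 7233 genes passed the usage test, 47 of them with a transcript whose mean usage moved by at least 0.1 of the gene.

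The smallest usage p belonged to 1700037H04Rik, where the retained-intron transcript 1700037H04Rik-204 went from 20.8% ± 3.10 to 53.1% ± 2.53 and the protein-coding 1700037H04Rik-202 from 69.5% ± 3.01 to 41.8% ± 2.96 (usage adjusted p = 9.67e-16, diffSpliceDGE). In Tlcd1, the retained-intron Tlcd1-206 went from 0.165% ± 0.405, with reads in ctrl 9 alone of the ctrl animals, to 22.8% ± 7.89, and the protein-coding Tlcd1-208 from 27.1% ± 2.16 to 9.34% ± 1.13 (usage adjusted p = 2.64e-14, diffSpliceDGE). Retained-intron Ergic1-204 rose in usage from 3.09% ± 1.19 to 22.3% ± 4.32 against Ergic1-206 from 72.8% ± 6.41 to 59.4% ± 5.69 (usage adjusted p = 4.83e-09, diffSpliceDGE). In Pepd, a dipeptidase gene, the protein-coding Pepd-201 went from 26.9% ± 5.71 to 55.8% ± 3.03 and the retained-intron Pepd-202 from 68.6% ± 5.90 to 39.1% ± 4.46 (usage adjusted p = 3.64e-06, diffSpliceDGE). In 4931406C07Rik the protein-coding 4931406C07Rik-201 went from 59.7% ± 8.04 to 83.1% ± 4.4, and 4931406C07Rik-202, with a start 4611 nt away, from 34.7% ± 7.93 to 13.6% ± 4.22 (usage adjusted p = 7.76e-06, diffSpliceDGE). Tspan18-205 starts at 93312515 on the minus strand of chromosome 2, 21972 nt from the start of Tspan18-202 at 93334487, and Ergic1-204 starts 62694 nt from Ergic1-206 on chromosome 17. Rab34-201 and Rab34-203 start 349 nt apart, at 78188430 and 78188779 on chromosome 11.

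**Figure D4:**
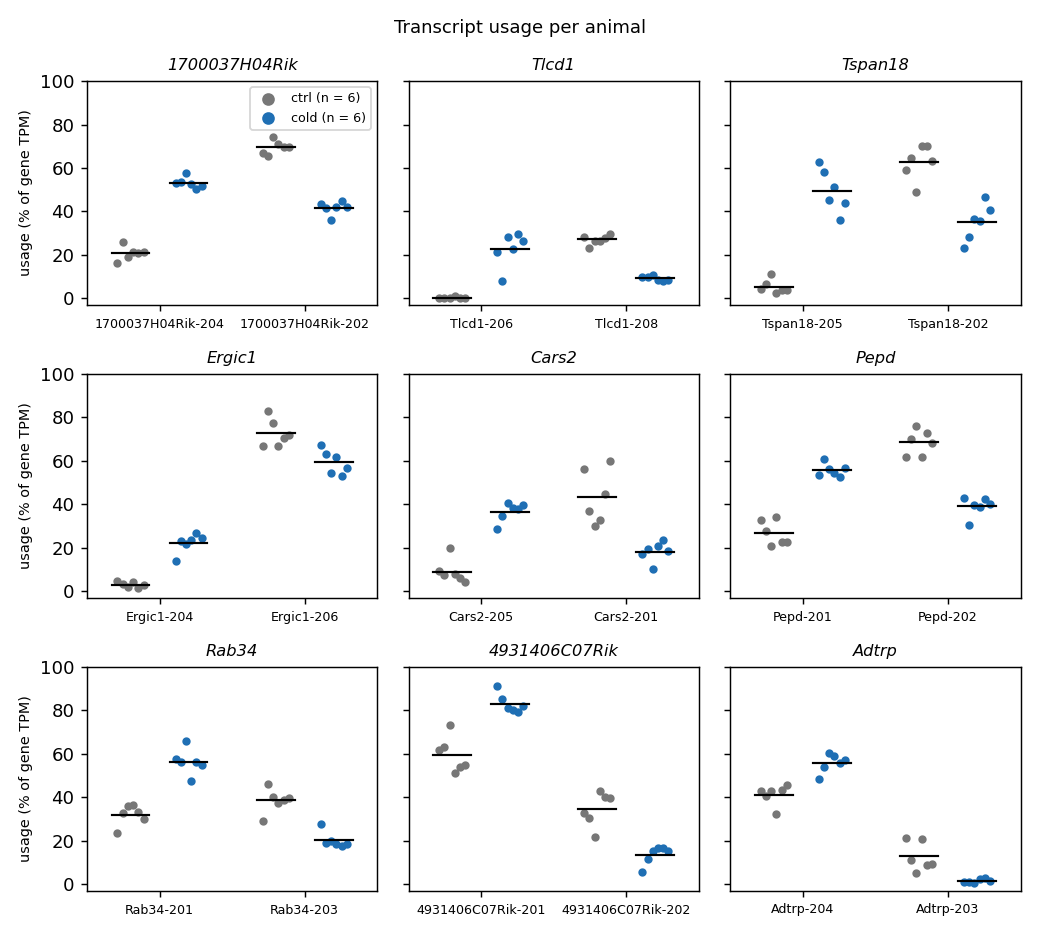
Usage, in percent of the gene's summed TPM, of the transcript that gained and the one that lost most in 9 genes past the usage test, one point per animal, ctrl in grey and cold in blue (n = 6 each), bars at the mean. In Rab34 the means cross from 32.0% and 38.6% in ctrl to 56.4% and 20.2% in cold.

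Adtrp, Cars2 and Acsl5 may have been singled out by the study on these animals, so their changes are not independent evidence. Adtrp, whose gene rose by 1.76 ± 0.21 (adjusted p = 4.03e-05, edgeR), had Adtrp-204 at 41.3% ± 4.73 in ctrl and 55.8% ± 4.30 in cold and Adtrp-203 at 12.8% ± 6.69 and 1.58% ± 0.94 (usage adjusted p = 3.50e-03, diffSpliceDGE). Acsl5, an acyl-CoA synthetase, rose as a gene by 0.99 ± 0.13 (adjusted p = 3.10e-05, edgeR), with Acsl5-201 at 51.7% ± 4.45 and 40.5% ± 2.49 and a usage adjusted p of 0.75 (diffSpliceDGE). In Ppargc1a, Ppargc1a-203 was at 90.6% ± 5.04 in ctrl and 63.0% ± 11.4 in cold (usage adjusted p = 0.15, diffSpliceDGE; 0.0393 without cold 4, where it was at 85.3%). The largest usage changes were -2.86 percentage points in Pparg and 1.59 in Lpin1 (usage adjusted p = 0.914 and 1, diffSpliceDGE). Among the 88 genes, the gaining transcript was protein-coding in 65, a retained intron in 8 and a decay target in 6, and the losing one in 58, 13 and 7. The gaining and losing transcripts started over 500 nt apart in 40, and 38 of the 88 did not pass the gene test.

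The usage count depended on the test and on a few libraries. It was 14 with Simes-adjusted transcript tests, by which Pepd, Rab34 and Adtrp no longer passed (adjusted p = 0.445, 0.763 and 0.0924), 195 with limma's diffSplice, 53 without ctrl 2 and cold 15, and 211 without cold 4. Those with a change of at least 0.1 numbered 9, 103, 26 and 109. In simulated data the main usage test made 34 false calls beside 134 of 188 true ones, so the 88 hold an unknown number of false calls.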

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

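Single animals standing far from the rest of their group were searched in 202 groups of 6 values with Dixon's test, which chance alone passes in about 1 of 20 groups, or 10.1 here, and 27 values passed. Apart from the counts of splits and the overall usage bound, the tests of explanations were set or reset after the result was seen. Cold 4, the most deeply sequenced library at 31.4 M reads against 17.0 to 20.8 M in the other cold animals, had 10 of the 27. It was the highest cold animal for Fabp3 (3400 CPM, others 2090 to 2470), erythroid markers (0.136% of reads, others 0.0615% to 0.0867%), Rab34-203 usage (27.6%, others 17.8% to 19.9%), Ppargc1a-203 usage (85.3%, others 53.0% to 61.9%) and Lpin1-202 usage (24.4%, others 0.0% to 5.95%). It was the lowest for Hsd17b7 (20.5 CPM, others 30.97 to 37.9), Pparg-202 usage (8.55%, others 11.5% to 12.9%), Acsl5-205 usage (30.1%, others 50.1% to 55.5%) and endothelial markers (0.137%, others 0.160% to 0.173%).

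Ctrl 6 stood apart in 4 values, as the highest ctrl animal for Cars2-205 usage (19.8%, others 4.13% to 9.32%), Ppargc1a-202 usage (17.2%, others 0.0%) and Lpin1-202 usage (30.4%, others 0.0% to 10.4%), and the lowest for Per3 (62.3 CPM, others 75.4 to 84.1). Cold 11 was lowest for Tyms (7.49 CPM, others 9.60 to 10.9), Ddx58 (6.52 CPM, others 8.18 to 9.14) and 1700037H04Rik-202 usage (36.2%, others 41.8% to 44.9%). Cold 7 was lowest for Tlcd1-206 usage (7.94%, others 21.4% to 29.5%) and Pepd-202 usage (30.6%, others 38.8% to 42.9%). Ctrl 10 was highest for Car3 (2590 CPM, others 1440 to 1800) and lymphocyte markers (2.32e-03% of reads, others 1.16e-03% to 1.52e-03%). Ctrl 9 was highest for Slc25a1 (1270 CPM, others 711 to 862) and Tlcd1-206 usage (0.991%, others 0.0%). Ctrl 2 was highest for Gm42418 and Lars2 (11.4% of reads, others 0.137% to 0.319%) and for transcripts annotated to nonsense-mediated decay (2.77%, others 1.47% to 1.63%). Cold 12 was highest for Gm42418 and Lars2 (1.56%, others 0.116% to 0.575%), and cold 15 lowest for Pnpla2 (2100 CPM, others 2410 to 2600).

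For the fall of fatty acid synthesis genes, skeletal muscle markers, all 20 of which passed the count filter in this tissue, took at most 0.689% of reads (cold 15, with Mb at 201 CPM). More muscle RNA in the cold samples is argued against as the whole cause, since with the muscle score in the model 11 of the 12 members stayed lower and the median went from -0.96 to -0.92. An earlier bound, that the 95% interval of that median lie below -0.48, was not met (-1.23 to -0.18) and was replaced, because it measures the spread between members rather than the effect of the score. Fewer adipocytes were weighed with 10 adipocyte genes outside the list, of which 5 were higher and 1 lower in cold. Their median was 0.23 (95% interval -0.18 to 0.56), above the list's, so these genes did not fall with the list. The risers, Lpl, Cd36, Cidec, Slc2a4 and Fabp4, belong to other lists that rose in cold. Their levels therefore cannot stand for the number of adipocytes. Fewer adipocytes would raise the relative RNA of other cell types. Median log2 fold changes were 0.05 for endothelial, 0.09 for macrophage, -7.1e-04 for mural cell, 0.11 for progenitor and 0.03 for erythroid markers. Those of Schwann cell and neuron, lymphocyte and skeletal muscle markers were -0.12, -0.54 and 1.06, muscle varying widely between libraries. Outside muscle none exceeded 0.11, which argues against fewer adipocytes as the whole cause of a list median of -0.96. An effect of cold itself, of single housing, or of feeding and energy state that cold changes, stays open and was not tested.

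The fall of mitochondrially encoded protein genes was weighed in the same way. Scaling is argued against by a median of -0.46 under library totals, the value nearest 0 of the scalings tried, with -0.55 under TMM and RLE factors. Skeletal muscle RNA is argued against by 8 of 8 members that stayed lower with the muscle score (median -0.50), although the earlier bound on the interval (-0.27) was missed at -0.22. Less mitochondrial RNA of every kind was weighed with the ribosomal RNAs mt-Rnr2, at 0.54 ± 0.22 (SE), and mt-Rnr1, at 0.40 ± 0.35. They lay 4.84 and 2.73 standard errors above the list's median, with no error counted for that median. An earlier bound, a rise of mt-Rnr2 past the test, was missed (adjusted p = 0.0893, or 1.71e-03 without ctrl 2 and cold 15, edgeR). Their reads thus did not fall with the protein genes. In poly(A) RNA such reads depend on polyadenylation and capture, so this explanation is not decided. Changed polyadenylation or capture of mitochondrial RNA, and an effect of cold or single housing on transcription or turnover, stay open and were not tested.

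Changes in transcript usage were weighed against skeletal muscle RNA, which carries isoforms of its own. With the muscle score in the model, a fit added after other results had been seen, 66 of the 88 genes stayed called, or 75.0%, which did not reach the 80% set before its result was seen and decides nothing alone. Muscle RNA as the whole cause was also weighed with the 3 cold animals below the ctrl mean share of muscle markers. They were set beside the 3 ctrl animals above it (mean shares 0.0545% and 0.150%). With less muscle RNA in cold, the most changed transcript of all 88 genes kept its direction. The median over genes was 0.99 of the reported usage change (95% interval 0.94 to 1.10, which does not measure the spread between animals). These genes and transcripts were chosen by a test that included the same animals, which favours a kept direction among them. The comparison therefore cannot decide, and muscle RNA as a cause of the usage changes is not decided. An effect of cold or single housing on promoter choice or splicing stays open and was not tested.

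Whether other groupings of the animals give results as large was counted over 100 of the 462 splits into 6 and 6, the real split included. Only the real split (1 of 100) reached 4380 genes, and the highest other gave 2. The same held for transcripts (1 of 100, 3123 against 5) and for usage (1 of 100, 88 against 26). The other splits mix cold and ctrl on each side, which widens the spread, so they do not show how many calls are false. The split with 26 usage genes set ctrl 2, 5 and 6 and cold 4, 7 and 11 against the rest, mostly low against high mouse numbers. Chance cannot be excluded for the number of lists called by camera at its preset correlation. There 28 of 100 splits gave 11 or more, the highest other 16 and the median 8. The list descriptions therefore rest on the counts of members past the gene test, read against the 31.6% of all genes that passed, and on the estimated correlation.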

How the results depend on the processing

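No paired analysis was possible because the mouse numbers of the groups are all different. The alternatives without both ctrl 2 and cold 15, or without Npr3, were chosen after seeing the data. The white adipocyte share changed direction without Npr3 (-6.03e-04 points, adjusted exact p = 0.886, against 0.0384). No other called value changed direction in any alternative, and no gene called in both changed direction. Gene counts stayed within 1.5 times those reported in every alternative but library totals (1409 lower). Leaving out each animal gave 2023 to 2605 genes higher and 1836 to 2481 lower, with 329 to 375 and 332 to 399 at least 2-fold. Transcripts numbered 1236 higher and 788 lower without both ctrl 2 and cold 15, 1906 lower with DESeq2, and 682 lower, 283 of them 2-fold, without a filter, where more transcripts were tested. Leaving out each animal gave 1461 to 2088 higher and 952 to 1555 lower transcripts, 413 to 521 and 374 to 539 of them 2-fold. Usage called 14 genes with Simes tests, 195 with limma's diffSplice (70 shared with the 88), 53 without both animals (49 shared), and 61 to 211 with each animal left out. With a usage change of at least 0.1 these were 9, 103, 26 and 35 to 109. The high ends came without cold 4; the cause was not tested. Lists higher in cold went from 7 to 1 with an estimated correlation and 6 to 9 with each animal left out. Lists lower went from 4 to 0 and 3 to 6. With fry, which asks whether a list moves at all and not whether it moves more than other genes, 11 lists were higher and 5 lower. With TPM shares, which include ctrl 2 and its TPM in transcripts of short effective length, the mitochondrial share differed by -4.62 points (adjusted exact p = 0.389), endothelial markers by 0.0124 (0.0238) and progenitor markers by 3.30e-03 (0.0238); the cause was not tested. The lymphocyte share differed by -5.80e-04 points without ctrl 2 and by -5.81e-04 without cold 16 (adjusted exact p = 0.0303 and 0.0227), with a range of -5.81e-04 to -3.49e-04. At these depths the simulated 1.5-fold changes were found for 48.4% of genes and 9.68% of transcripts. Over single named genes, 7 of the refits gained and 2 lost a call.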

Other observations

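Every test here was chosen after the data were seen. Genes were grouped by the stem of their symbol. Of 212 genes with the Slc stem, most of them solute carriers, 62 were higher and 30 lower in cold, against 34.3 and 32.6 expected from all genes (exact hypergeometric test, adjusted over 107 families, p = 2.44e-04). Of 54 genes with the Rab stem, small GTPases of vesicle traffic and their partners, 22 were higher and 8 lower (adjusted exact p = 1.52e-03). Rab37 rose from 1.10 to 6.26 CPM and Rab3a from 15.8 to 32.6 CPM (log2 fold changes 2.49 ± 0.18 and 1.05 ± 0.13 (SE); adjusted p = 6.51e-08 and 1.38e-05, edgeR, n = 6 each). Of 31 genes with the Col stem 14 were lower and 4 higher (adjusted exact p = 5.60e-03), with Col7a1 at -1.57 ± 0.15 and Col6a6 at -1.75 ± 0.26. The risers included Col4a3bp, a ceramide transfer protein and not a collagen, and with the Slc stem Slc9a3r1, a scaffold protein and not a carrier. Genes are not independent replicates, and by camera none of these families passed (adjusted p = 0.339, 0.339 and 0.158; 0.987 for each with an estimated correlation). All 3 directions were kept under RLE factors and library totals.

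Long non-coding RNA genes past the test were mostly lower in cold, a pattern that is a hypothesis from these data. They numbered 193 lower and 74 higher, so 72.3% were lower, against 46.8% of the protein-coding genes that passed (Fisher's exact test across genes, p = 4.81e-16). With library totals the shares were 66.3% and 30.3% (Fisher's exact p = 4.52e-29), and with an effective length offset 68.8% and 44.8% (exact p = 4.17e-12). Without ctrl 2 and cold 15 they were 70.3% and 45.3% (exact p = 1.38e-12). Genes are not independent replicates, so these p-values do not measure the spread between animals. Overlapping gene pairs on one strand cannot be told apart in the estimates, and the explanation was not tested.

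The log2 ratio of mt-Rnr2 to the mitochondrial protein genes was -3.90 ± 0.56 in ctrl and -2.82 ± 0.17 in cold (SD, n = 6 each; exact permutation p = 8.66e-03), a difference of 1.08, with 3 of 6 cold animals above every ctrl animal. mt-Rnr2 was at 23600 CPM in ctrl 2 and 8650 to 14540 CPM in the other ctrl animals, against 15550 to 23500 CPM in cold. Retained-intron transcripts took 2.64% ± 0.24 of reads in ctrl and 2.37% ± 0.11 in cold (exact permutation p = 0.0368, adjusted over 4 added shares 0.147), and 0.0346 after adjustment without ctrl 14. Processed transcripts took 1.68% ± 0.12 and 1.55% ± 0.11 (exact permutation p = 0.0779, adjusted 0.156).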
